A study of Dugesia japonica with 4 samples.

How the data were processed

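RNA from amputated heads of the planarian Dugesia japonica was compared between worms that had regrown their heads in BaCl2 and untreated controls. The 4 libraries were 2 control and 2 BaCl2 replicates, per the labels biological replicates of 25 worms each, with 35 days in 1 mM BaCl2 for the treated worms. Nothing says that a replicate number marks a day or culture shared by a control and a BaCl2 library. The design text also speaks of 3 replicates per treatment and of starved worms; the third replicates were not analysed here. The labels do not say whether the worms of the 4 libraries were fed, so a difference in feeding between the groups stays open.

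The authors deposited 3 tables of assembled transcript features, with protein names, lengths and contig positions. In all 3 tables the authors gave the expression values as FPKM (fragments scaled by feature length and library size), per the file headers. A log2 fold change column stands beside them, per the file headers, as BaCl2 over control. A p-value and a q-value column from the authors' own comparison complete each deposited table. The submitters' processing notes name Bowtie, TopHat2 2.0.13, TopHat, Cufflinks 2.2.1 and Cuffdiff without their roles, and poly(A) TruSeq libraries. The genome build is not given in the sources used here, and the loci are contigs.

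1 table pooled the replicates of each group (15850 features) and the other 2 each held 1 control and 1 BaCl2 library, scaled separately. Each pooled value was the same weighted sum of the replicate values, within 0.1% in 15202 of the 15204 features with both pooled values and both replicate values. The weights (0.640 and 0.357 for the control libraries, 0.645 and 0.358 for the BaCl2 libraries) therefore put the 4 libraries on 1 scale. In 440 features of the pooled table the BaCl2 value was blank. For 197 of these the control libraries were at 0 and the value in the control column equalled the BaCl2 mean, so the replicate tables were used instead. For the 376 features missing from a replicate table, 752 library values were worked out from the pooled table, 61 of them above 0. In 87 names the replicate 2 table had NA in place of a hyphen. Names were taken from the pooled table. Where missing there, or where the BaCl2 value was blank, they came from the replicate tables. In 117 of the 440 blank features the pooled table had the organism in the column of mouse symbols. After this 7971 features had a protein name and 4421 a name other than uncharacterized.

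Feature lengths had a median of 332 nt, and 26.0% were under 200 nt. FPKM values were turned back into fragment counts with a fragment length model (mean 200 nt, SD 80 nt, from 28 to 440 nt). In each library 99.79% to 99.88% of the checked values came out whole within a tolerance of 0.1 fragments. This gave 5901088 and 8304591 fragments for the control libraries and 3395457 and 6875634 for the BaCl2 libraries. A single fragment in a feature of 100 nt stood for 11.1 to 22.3 FPKM, and in a feature of 400 nt for 0.146 to 0.293 FPKM. Short features therefore had large FPKM values from few fragments. The fragments of a library are not independent molecules, so floors cover counting error only.

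The comparison was a two-sided limma 3.58.1 fit (R 4.3.3; eBayes with a mean trend) on log2(FPKM + 1), without a block, over features with a mean of at least 1 FPKM. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and 2 residual degrees of freedom remained. Features that differed at least 2-fold in both pairs of libraries with the same number were counted beside the crossed pairs, without a test. 30 lists, 22 of functions and 8 of cell type markers, were matched by patterns on the deposited protein names, gene names, and mouse and C. elegans gene symbols. Each with at least 5 tested features was tested with camera (preset correlation 0.01), with camera under an estimated correlation, and with fry. The function lists were potassium channels, TRP channels, voltage-gated calcium and sodium channels, chloride channels, innexins, ion pumps and ion-coupled transporters, neurotransmitter receptors, calcium sensing, chaperones, redox and detoxification, apoptosis, Wnt signalling, BMP and TGF-beta signalling, FGF receptors, homeobox genes, tubulins, extracellular matrix, ribosomal proteins, oxidative phosphorylation, proteasome, core histones and innate immunity. The marker lists covered neurons, intestine, muscle, cilia and epidermis, neoblasts, eyes, protonephridia and mucous glands. Features named in the text were, per direction, the 12 with the largest fold among those past the threshold with a mean of at least 5 FPKM. With fewer than 5 passing, the 12 with the largest worst-case difference over the 4 library pairs stood in. From each list came up to 4 members past the threshold, or else the 2 with the highest mean FPKM. TRP, potassium and chloride channels and innexins were to be named wherever they passed. These choices were made before the data were examined.

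Alternatives fixed in the same way were pseudocounts 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, a replicate block, no trend, features of one annotation summed, each library left out, and a q-value under 0.01 for the deposited comparison. Chosen after seeing the data were fits of features with at least 40 or 100 recovered fragments over the 4 libraries, of at least 200 or 400 nt, and limma voom on recovered fragments (at least 40), with fragment totals as library sizes or with the libraries scaled as deposited. The naming rule was repeated among features of at least 200 nt with at least 100 fragments, 10 per direction. Gene ontology terms with at least 10 features were tested too, again after seeing the data. Where a library was left out, the lone library of its group was assumed to vary like the other group.

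The test was tried on simulated data with 200 changed features. Over all 15683 features it called 2% of those raised 4-fold, 6% of those lowered 4-fold, 94% of those raised 16-fold and 38% of those lowered 16-fold, with 7 false calls. Over the 7982 features with at least 100 fragments it called 96% to 100% of them, with 2 false calls. The simulation gave every feature the same spread between libraries. In the data 877 of the 7982 differed at least 2-fold between the BaCl2 libraries and 287 between the control libraries, so these shares need not hold. Camera called 10 of 10 simulated lists of 30 features shifted 1.5-fold and 0 of 30 unshifted lists. The simulated features were drawn independently, so false calls from features that vary together could not appear. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.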

Results

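Planarians are freshwater flatworms that regrow a lost head, and barium ions block potassium channels. Expression was measured by RNA sequencing in heads that had regrown in 1 mM BaCl2 over 35 days, and in control heads. The labels give no exposure or regrowth for the control heads, so effects of barium and of head regrowth cannot be told apart. There were 2 libraries per group, each from 25 worms. The control libraries held 5901088 and 8304591 recovered fragments and the BaCl2 libraries 3395457 and 6875634. Of the 15850 assembled features, 15683 passed the expression filter and 7982 had at least 100 fragments over the 4 libraries. In features of 800 nt or more, log2(FPKM + 1) correlated across features at 0.985 between the control libraries, at 0.961 between the BaCl2 libraries and at 0.919 to 0.940 between groups. In those under 100 nt the same values were 0.150, 0.360 and 0.0815 to 0.240. Features are not independent replicates.

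The first comparison asked which transcripts differ between heads that had regrown in BaCl2 and control heads, the series being about adaptation to an electrochemical perturbation. A ferritin transcript (TCONS_00005540; ferritin stores iron) fell 525-fold, from 1727 ± 73.3 FPKM in control heads to 3.29 ± 2.89 FPKM in BaCl2 heads (SD, n = 2 each), 324-fold without BaCl2 replicate 2 and 1388-fold without BaCl2 replicate 1. The SPSB transcript, named after SPRY domain proteins with a SOCS box, fell 504-fold, from 328 ± 2.86 to 0.652 ± 0.00789 FPKM. Its BaCl2 values rest on 7 and 12 fragments, too few for the precision that this SD shows. A set of 16 tubulin features, the subunits of microtubules, fell with log2 folds between -4.48 and -2.29. Among them was a tubulin alpha (TCONS_00000243) at 24.4 ± 1.32 FPKM in control and 0.757 ± 0.320 FPKM in BaCl2 heads (11 and 10 BaCl2 fragments). A kinesin-like motor protein fell from 12.4 ± 2.78 to 0.751 ± 0.524 FPKM (16.5-fold, and 11.1- to 32.6-fold with each library left out), with 7 and 4 BaCl2 fragments. Gamma-glutamyltranspeptidase 1, an enzyme of glutathione breakdown, fell from 90.0 ± 2.35 to 17.9 ± 5.26 FPKM. The only named feature that rose in this test was Slc2a-1, of the glucose transporter family, from 4.85 ± 2.21 to 42.1 ± 8.37 FPKM, which was 8.68-fold.

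These calls came from limma on the 7982 features with at least 100 fragments, a restriction chosen after seeing the data, which called 113 features (16 higher and 97 lower) against 1505 at unadjusted p under 0.05. Ferritin had a log2 fold of -8.84 (SE 0.50, adjusted p = 0.000757), SPSB -7.64 (SE 0.25, adjusted p = 0.00012) and Slc2a-1 2.92 (SE 0.34, adjusted p = 0.0179). The kinesin-like protein had -2.95 (SE 0.33, adjusted p = 0.0142), protein FAM221B -2.52 (SE 0.30, adjusted p = 0.0179) and gamma-glutamyltranspeptidase 1 -2.30 (SE 0.30, adjusted p = 0.0262). Each of these 6 and 5 of the 16 tubulins, so 11 of the 33 named features called, also passed with median-ratio rescaling and with a pseudocount of 0.1. The replicate block, a pseudocount of 5 and the fits without 1 library called more features than this fit, so passing there was no check. With median-ratio rescaling these 11 were the only named features among 45 calls, and with a pseudocount of 0.1 16 of the 33 passed, among 53 calls. Mitotic phosphoprotein 44, linked by name to cell division, also missed the threshold without control replicate 1 (adjusted p = 0.0744; log2 fold -1.63, adjusted p = 0.0434 with all libraries). The count was 225 without control replicate 1 (40 of them higher), 347 without control replicate 2 (136 higher), 242 without BaCl2 replicate 1 (43 higher) and 957 without BaCl2 replicate 2 (237 higher), with 104 to 112 of the 113 features among them.

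Further named features fell in that fit, among them 2 of the 17 members of the cilia and epidermal list with at least 100 fragments. Tektin-3 (TCONS_00015005), a filament protein of ciliary microtubules, had 57.4 ± 2.59 FPKM in control and 1.45 ± 2.05 FPKM in BaCl2 heads (log2 fold -4.89, SE 0.60, adjusted p = 0.0206), with 132 against 2 fragments. A radial spoke head protein 3 homolog, part of the machinery that bends cilia, fell with a log2 fold of -2.76 (SE 0.43, adjusted p = 0.0444), to 0.835 ± 1.03 FPKM in BaCl2 heads. Protein FAM154A (log2 fold -3.27), a phosphotransferase (-3.25), the RNA-binding heterogeneous nuclear ribonucleoprotein A2 (-3.21) and a cytoplasmic poly(A) binding protein (-2.29) fell as well. Of these, FAM154A had 5.10 and 1.28 FPKM in the BaCl2 libraries, the phosphotransferase 2.26 and 0.256, and the ribonucleoprotein 1.63 and 0.193. The size of their falls therefore depends on the BaCl2 library. A myosin light chain kinase (TCONS_00014899) fell with a log2 fold of -2.02, while another feature of that name (TCONS_00007185) had 1.48 and did not pass (adjusted p = 0.0762). Features that were higher in BaCl2 heads but did not pass included the TGF-beta pathway inhibitor SMAD6/7-2 at 2.05 (SE 0.40, adjusted p = 0.078) and the calcium sensor calmodulin family member Cmd 1 at 1.44 (SE 0.27, adjusted p = 0.0743). A calmodulin feature at 2.18, thionin at 1.24, the metalloprotease ADAMTS5 at 1.10, glyoxylate reductase at 1.18, two-pore calcium channel protein 2 at 1.19 and the neuronal G protein subunit G(O) alpha at 1.06 did not pass either.

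**Figure D1:**
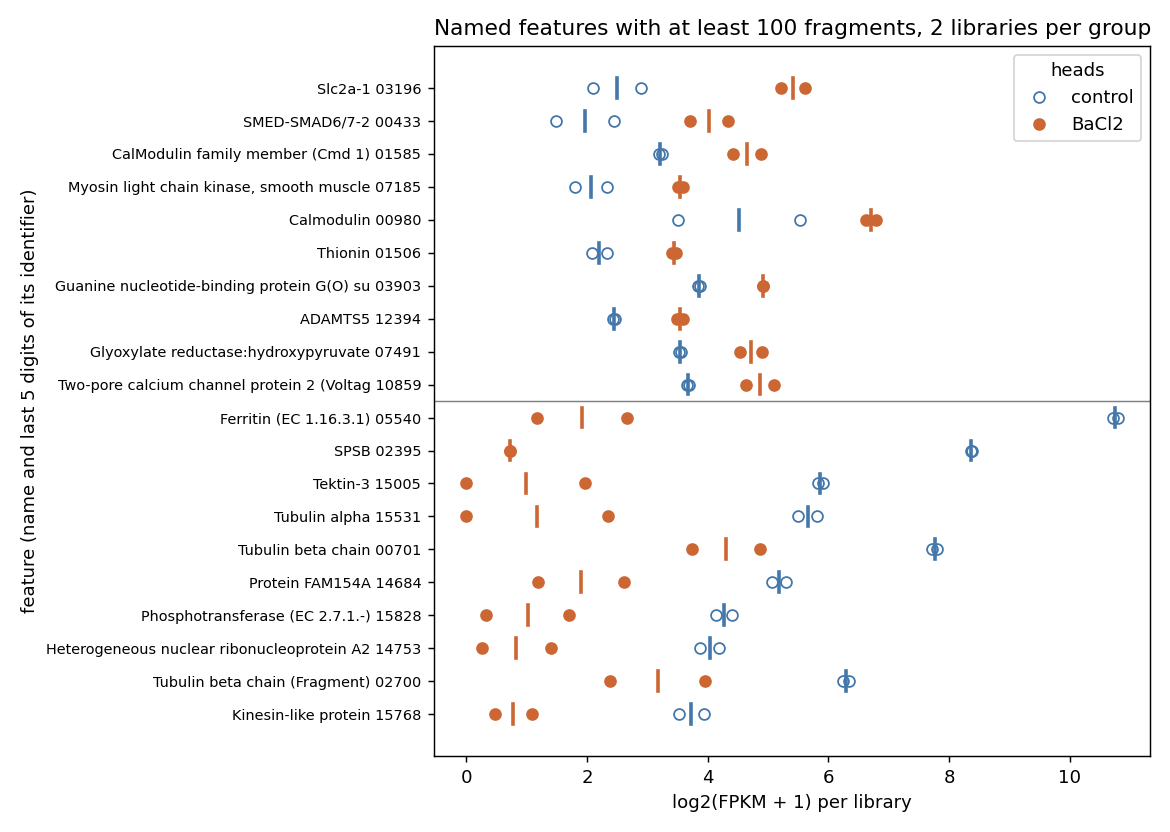
Expression of the 20 named features of the added naming rule (at least 200 nt and 100 fragments), as log2(FPKM + 1) in each of the 2 control (open) and 2 BaCl2 (filled) libraries, with bars at the group means. Ferritin and SPSB show the widest gaps (log2 folds -8.84 and -7.64), and of the 10 higher features only Slc2a-1 passed the test.

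Unnamed features, singled out after their values were seen, showed the same sharp presence or absence. The most abundant, TCONS_00015029, had 36548 ± 3333 FPKM in control and 51.3 ± 11.9 FPKM in BaCl2 heads (SD, n = 2 each), a 712-fold lower level that also passed over all features (limma adjusted p = 0.0328). TCONS_00015862 was 107-fold lower (adjusted p = 0.000375 among features with at least 100 fragments). TCONS_00010587 was at 0 in both control libraries and had 491 and 1254 fragments in the BaCl2 libraries, which was at least 284-fold higher with a floor of 3 fragments per control library (adjusted p = 0.000314). TCONS_00000554, with 0 and 0 against 84 and 145 fragments, was at least 41.5-fold higher (adjusted p = 0.00289).

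Over all 15683 features limma called 20, 7 higher and 13 lower, against 1770 at unadjusted p under 0.05. Of the 13 lower features 4 were named. They were SPSB (adjusted p = 0.0328), cubilin, an endocytic receptor of excretory tissue, a putative pre-mRNA splicing factor and Star lipid transfer protein 7. The last 3 were at 0 in both BaCl2 libraries, with 16, 21 and 41 control fragments in all and adjusted p values of 0.0328, 0.0328 and 0.0398. All 7 higher features were unnamed, under 200 nt, at 0 in both control libraries, and had a median of 14 fragments. With a replicate block 0 features passed, with 1575 at unadjusted p under 0.05, and 0 passed without any 1 of the 4 libraries, with 1048 to 2407 at unadjusted p under 0.05. The restriction to at least 100 fragments gave 113 calls, 5 of them among the 20, and the block gave 948 there, 404 higher and 544 lower.

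Because 0 named features passed higher and 4 lower, the naming rule took the largest worst-case differences. The 12 higher features were all under 200 nt and had 11 to 26 fragments, and none passed. They were serine/threonine kinase, glutamate receptor-interacting protein 1, NPYR-14 (a neuropeptide Y receptor by name), surface protein, ribose 5-phosphate isomerase A, GCR010, the vesicular glutamate transporter Slc17a-1, a TRP cation channel, an elongase of very long chain fatty acids, a calcium-transporting ATPase, beta arrestin 1 and neuropeptide Y prohormone-4. Their adjusted p values ran from 0.116 to 0.479. The first 7 were at 0 in both control libraries. Beside ferritin, SPSB and the 3 at 0 named above, the 12 lower features held 7 that did not pass and were at 0 in the BaCl2 libraries, each with 11 to 21 control fragments. These were exportin-5, CyclinA-like protein, phosphodiesterase, RNA helicase DHX35, calcium homeostasis endoplasmic reticulum protein, SJCHGC06824 protein and WD repeat-containing protein 35 (adjusted p = 0.10 to 0.316). Ferritin missed the threshold over all features (adjusted p = 0.087).

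Limma voom, which weights recovered fragments scaled by library totals, was another choice made after seeing the data and called 144 of 11186 features, 70 higher and 74 lower. Of the 41 named, 21 were higher and 20 lower. That scale moved log2 folds up by a median of 0.20 against the deposited one. With the libraries scaled as deposited voom called 211, 56 higher and 155 lower, and 14 of the 21 and 19 of the 20 named features still passed. On the library totals muscle proteins passed as higher, among them paramyosin with a log2 fold of 1.10 (SE 0.14, adjusted p = 0.0156), myosin regulatory light chain 2 with 1.08 (SE 0.15, adjusted p = 0.0204), troponin I with 0.80 (SE 0.15, adjusted p = 0.0456) and 2 titin features with 1.25 and 1.34. On the deposited scale paramyosin (adjusted p = 0.157), myosin regulatory light chain 2 (0.170) and troponin I (0.340) did not pass, and the titin features had 0.0504 and 0.0499. Calbindin-32 was higher on both scales, with 1.43 (SE 0.21, adjusted p = 0.0224) and 1.21 (0.0411 on the deposited one), and sarcoplasmic calcium-binding protein on library totals alone (1.26, SE 0.18, adjusted p = 0.0204, against 0.0765). Passing on both scales, with the folds on library totals, were the membrane scaffold flotillin-1 (1.41), the actin-severing protein severin (1.42), G(O) alpha (1.32) and Slc2a-1 (3.27, SE 0.50, adjusted p = 0.026). Lower on both scales were the cyclin-dependent kinase regulatory subunit with -1.35 (SE 0.25, adjusted p = 0.0456) and ribonucleoside-diphosphate reductase, which makes DNA precursors, with -0.99 (SE 0.19, adjusted p = 0.0484). Dyskerin (-0.95), which acts in ribosome assembly, and the zinc transporter Slc39a-8 (-1.50) did the same, while the neoblast and proliferation list did not pass with voom (adjusted p = 0.412). In limma on log2(FPKM + 1) with at least 100 fragments these features did not pass, except Slc2a-1.

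The next comparison asked whether whole groups of genes moved, with 30 lists of which 29 could be tested and 7 passed camera with its preset correlation, 4 higher and 3 lower. With an estimated correlation none of the 7 held, the lowest adjusted p being 0.600. That version leaves camera only the 2 residual degrees of freedom, so hardly any list could pass. Tubulins went from an unadjusted camera p of 4.87e-15 to 0.0295, so its loss does not decide against a list. By fry, which asks whether a list's features move one way on balance, the lowest adjusted p was 0.0699. Its mixed form, with features free to move either way, gave the 7 adjusted p of 0.00651 to 0.0484 and passed other lists too. The lists matched names, so they hold several features of 1 gene and some members that do other things.

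Tubulins were the clearest list: 50 of the 55 features were below 0 and the median log2 fold was -2.12 (camera adjusted p = 1.41e-13; adjusted p = 0.600 with an estimated correlation). None passed over all features, and 19 were lower when adjusted over the list alone. Of the 39 with at least 100 fragments, 16 fell and 23 did not pass. Voom called 2 tubulin alpha features higher, TCONS_00000340 with a log2 fold of 1.61 (SE 0.18, adjusted p = 0.0117) and TCONS_00015516 with 1.65 (SE 0.25, adjusted p = 0.0254), and 7 tubulins lower. With at least 100 fragments 25 tubulins were lower when adjusted over the list alone and these 2 were higher (0.00771 and 0.0151). The 6 features with over 5000 fragments had log2 folds from -0.52 to 0.33, including tubulin beta-2C chain at -0.07 and a tubulin beta fragment at -0.32. All tubulin features together held 8646 and 8226 CPM (fragments scaled to library totals) in control and 6852 and 9107 CPM in BaCl2 heads. In CPM, a scale that moved log2 folds up by a median of 0.20, features named alpha had a mean ratio of 1.15 (BaCl2 over control) and those named beta 0.88. On the deposited scale those named alpha summed to 4522 and 3743 FPKM in control and 2717 and 3481 FPKM in BaCl2 heads. A sum of FPKM weights short features: a 60 nt feature (TCONS_00001263) with 10 fragments made up 1180 FPKM of the sum in control replicate 1. The CPM and FPKM sums therefore differ by more than the scaling of the libraries. No feature sequences were compared, so which copy a fragment came from was not tested.

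**Figure D2:**
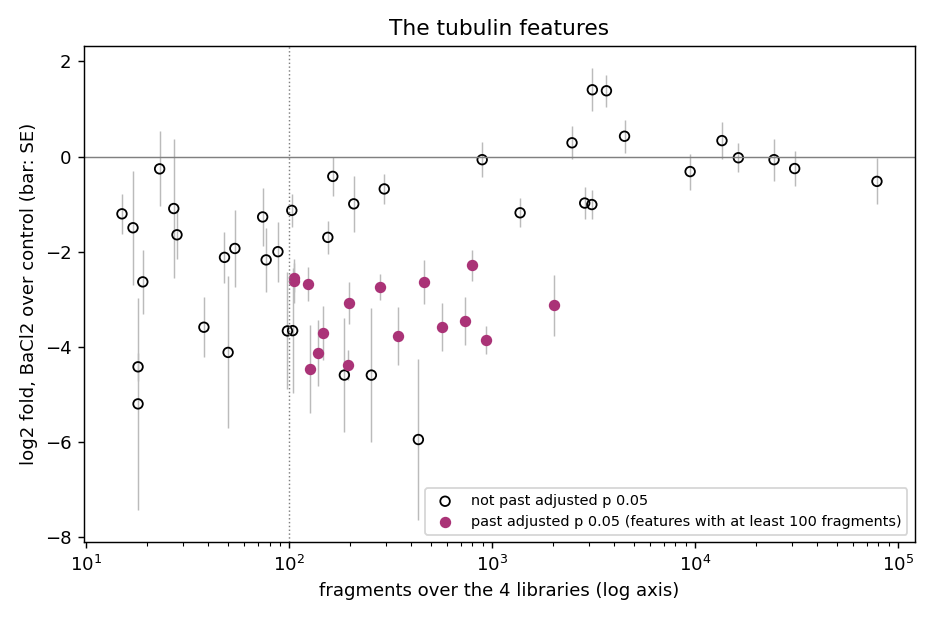
Log2 fold (BaCl2 over control, bars SE from all features) of the 55 tubulin features against their fragments over the 4 libraries on a log axis. The 16 filled points passed adjusted p 0.05 among features with at least 100 fragments, and the 6 features with over 5000 fragments lie between -0.52 and 0.33.

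Cilia and epidermal markers were lower, with a median of -0.56 and 7 of 32 features above 0 (camera adjusted p = 0.0187; adjusted p = 0.612 with an estimated correlation). None of its members passed over all features or when adjusted over the list alone. A radial spoke head protein 3-like feature had 273 ± 19.6 FPKM in control and 126 ± 81.0 FPKM in BaCl2 heads (log2 fold -1.28, adjusted p = 0.506), and a putative radial spokehead feature -0.23. Among features with at least 100 fragments 1 of 17 was above 0 (camera adjusted p = 0.00603; adjusted p = 0.776 with an estimated correlation). The call was lost without control replicate 2 (adjusted p = 0.412), without BaCl2 replicate 1 (0.0530), with features of at least 5 FPKM (0.0651) and with same-name features summed (0.202).

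Proteasome subunits, which break down tagged proteins, were lower with a median of -0.42 and 2 of 24 features above 0 (camera adjusted p = 0.0141; adjusted p = 0.600 with an estimated correlation). No member passed over all features and 1, the 26S regulatory subunit 12 at -3.41 with 68 fragments, passed when adjusted over the list alone. The most abundant alpha subunits had -0.27 and -0.41. The list missed the threshold without control replicate 1 (adjusted p = 0.0853), without control replicate 2 (0.0936) and among features with at least 100 fragments (0.120).

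Neuronal and synaptic markers were higher, with a median of 0.51 and 31 of 40 features above 0 (camera adjusted p = 0.00339; adjusted p = 0.600 with an estimated correlation). No member passed over all features, while Slc17a-1 and NPYR-14, with 14 and 18 fragments, passed when adjusted over the list alone. Neuropeptide-18 had 754 ± 30.6 FPKM in control and 1647 ± 371 FPKM in BaCl2 heads (log2 fold 1.11, adjusted p = 0.427), neuropeptide Y prohormone-4 had 6.99 from 25 fragments, and complexin-1, which acts in transmitter release, had 0.98. Choline O-acetyltransferase, the enzyme that makes acetylcholine, had 0.10. With at least 100 fragments 13 of 18 were above 0, the median was 0.34 and the list did not pass (adjusted p = 0.0977).

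Potassium channels, the targets of barium, were higher with a median of 1.02 and 8 of 9 features above 0 (camera adjusted p = 0.00448; adjusted p = 0.600 with an estimated correlation). None passed over all features, and when adjusted over the list alone 1 passed, the Shaw channel, at 0 in control and with 14 fragments in BaCl2 heads. The Shaker channel had 29.7 ± 1.43 FPKM in control and 64.5 ± 28.9 FPKM in BaCl2 heads (log2 fold 1.02, adjusted p = 0.487), and a large conductance calcium-activated channel had 1.41. The call was lost with features of at least 5 FPKM (adjusted p = 0.0951), and 4 of the 9 features had at least 100 fragments. With at least 100 fragments, the gene ontology term voltage-gated potassium channel activity had a median of 0.32. Of its 10 features 7 were above 0, and it did not pass camera (preset correlation, adjusted p = 0.069). Voltage-gated calcium and sodium channels, a list that also took in two-pore and amiloride-sensitive channels, had a median of 1.00 with 9 of 11 above 0 (camera adjusted p = 0.0103; adjusted p = 0.600 with an estimated correlation), with none passing over all features or when adjusted over the list alone. With at least 100 fragments the list had 3 features, and adjusted over these 3 two-pore channel protein 2 (adjusted p = 0.0122) and an amiloride-sensitive channel (0.0327) passed as higher, while over all 7982 they did not (0.112 and 0.199). Its calcium channel subunit alpha-2/delta-1 with the most fragments had -0.04, and a short feature of that name had 7.18 from 15 fragments. That list missed the threshold without control replicate 1 (adjusted p = 0.105), without BaCl2 replicate 2 (0.219), with features of at least 5 FPKM (0.234) and with same-name features summed (0.0894).

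Muscle markers were higher with a median of 0.35 and 28 of 36 features above 0 (camera adjusted p = 0.0103; adjusted p = 0.633 with an estimated correlation). None passed over all features or when adjusted over the list alone, and the list held several titin and tropomyosin features and a non-muscle myosin heavy chain at -0.04. Tropomyosin, which guards actin filaments, had 637 ± 83.5 FPKM in control and 823 ± 202 FPKM in BaCl2 heads (log2 fold 0.35, adjusted p = 0.686), and myosin regulatory light chain 2 had 0.85 (adjusted p = 0.468). The call held with at least 100 fragments (camera adjusted p = 0.00603; adjusted p = 0.776 with an estimated correlation) and was lost with same-name features summed (0.202). It was also lost without control replicate 2 and without BaCl2 replicate 2.

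**Figure D3:**
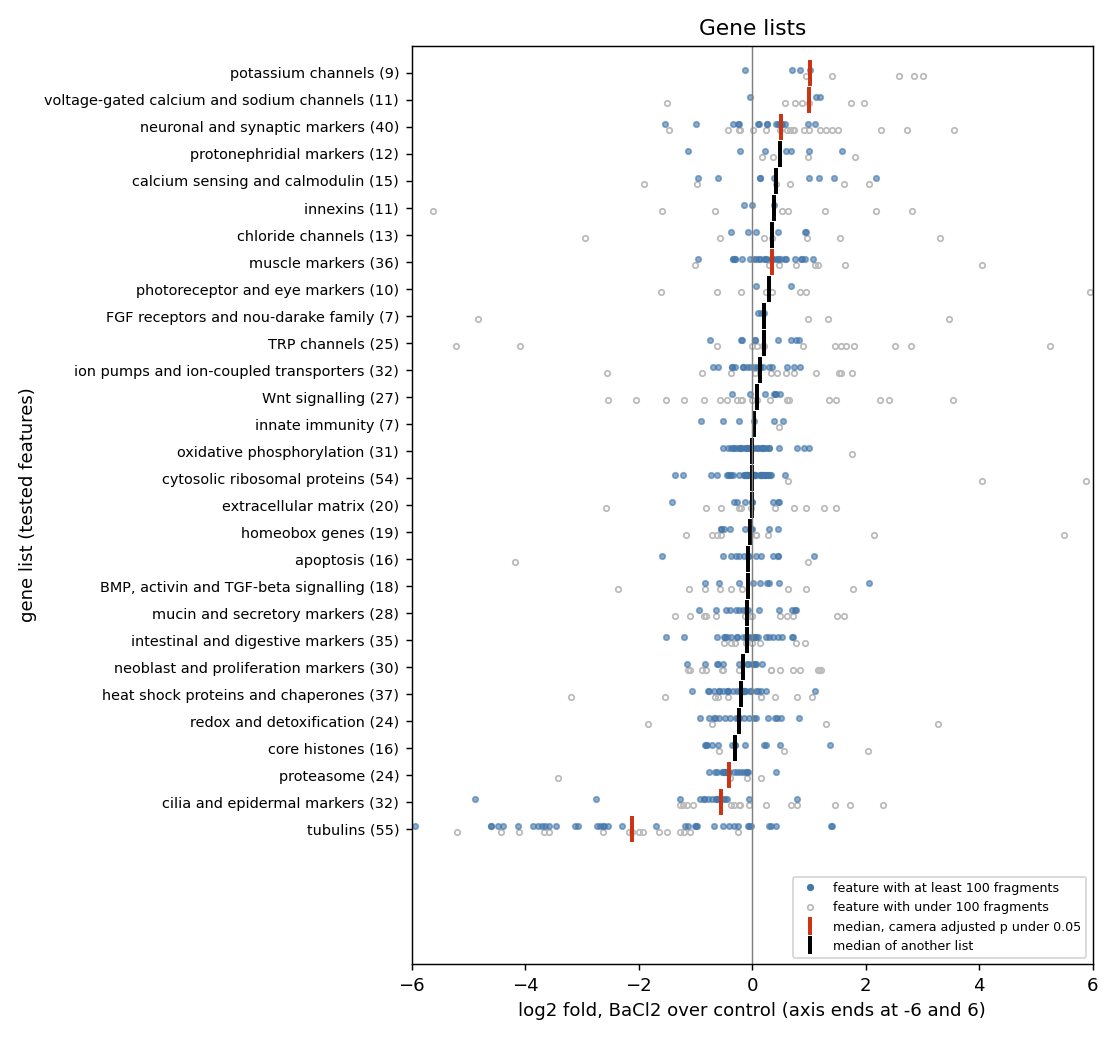
Log2 folds (BaCl2 over control) of the features of the 29 tested lists, with the number of features in brackets, blue points for features with at least 100 fragments, grey rings for fewer, and bars at the list medians. The 7 red bars mark lists past camera adjusted p 0.05 with the preset correlation, from tubulins at -2.12 to potassium channels at 1.02, and points beyond -6 and 6 are not drawn.

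Calcium sensing proteins did not pass over all features (median 0.42, 11 of 15 above 0, adjusted p = 0.128) and were higher among features with at least 100 fragments (adjusted p = 0.0453; adjusted p = 0.776 with an estimated correlation). Of its members calbindin-32, a calmodulin, sarcoplasmic calcium-binding protein and Cmd 1 passed there as higher when adjusted over the 9 features of the list alone (adjusted p = 0.0135 to 0.0262) but not over all 7982 (0.0743 to 0.154). A calcium-binding protein had 0.14 and a short calmodulin-related feature 2.06. The other ion channel lists did not pass, and no member of the TRP, potassium or chloride channel or innexin lists passed over all features. TRP channels had a median of 0.20 (adjusted p = 0.175), with the 2 most abundant, short features at 0.19 and -5.22. Chloride channels had 0.36 (adjusted p = 0.426), with a chloride channel protein at 1.54 and a bestrophin at -2.96. Innexins, which form gap junctions, had 0.38 (adjusted p = 0.911), with 2 short features at 1.28 and -5.62. Ion pumps and ion-coupled transporters had 0.14 (adjusted p = 0.275), with the proton pump subunit F at -0.16 and a short calcium-transporting ATPase feature at 7.29. Neurotransmitter receptors had 2 features and were not tested, a glycine receptor beta subunit at 0.99 and an acetylcholine receptor alpha-4 subunit at 0.34.

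Stress and signalling lists did not pass. Chaperones had a median of -0.21 (adjusted p = 0.184), with the 2 most abundant heat shock 70 features at -0.02 and -0.15. Redox and detoxification had -0.24 (adjusted p = 0.776), with 2 superoxide dismutase features at -0.26 and -0.29. Apoptosis had -0.07 (adjusted p = 0.933), with a short caspase-8 feature at 0.98. A 62 nt Bax inhibitor-1 feature had -4.18 (SE 3.98) from 1 BaCl2 library at 0, and the deeper TCONS_00003620 of that name -1.59 (adjusted p = 0.379), which passed with at least 100 fragments when adjusted over the list alone (0.0291) but not over all 7982 (0.0861). Wnt signalling had 0.08 (adjusted p = 0.426), with axis inhibition protein B at -0.01 and secreted frizzled related protein 3 at 3.53. BMP and TGF-beta signalling had -0.08 (adjusted p = 0.911), with 2 activin features at -0.18 and -1.12, and SMAD6/7-2 passed as higher with at least 100 fragments when adjusted over the 9 features of the list alone (adjusted p = 0.0155). FGF receptors and the nou-darake family had 0.21 (adjusted p = 0.298), with 2 features of an FGF receptor substrate at 0.09 and -4.84. Homeobox genes had -0.03 (adjusted p = 0.911), with the Hox protein DjAbd-Bb at -1.17 and a putative homeobox protein at 5.49. Innate immunity had 0.03 (adjusted p = 0.99), with a lipopolysaccharide-induced factor at 0.03 and a TNF receptor-associated factor at -0.90.

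Housekeeping and matrix lists did not pass over all features either. With voom on library totals ribosomal proteins (median 0.21, adjusted p = 0.0149) and oxidative phosphorylation (0.22, adjusted p = 0.0256) passed as higher (each adjusted p = 0.622 with an estimated correlation), and on the deposited scale they did not (adjusted p = 0.914 and 0.374). Ribosomal proteins, among them some mitochondrial ones, had a median of -0.0044 (adjusted p = 0.911), with L36a at 0.17 and S28 at 0.03. Oxidative phosphorylation had -0.0028 (adjusted p = 0.769), with a cytochrome c oxidase copper chaperone at -0.23 and ATP synthase subunit 9 at 0.08. Core histones had -0.31 (adjusted p = 0.778), with H2B at -0.13 and a short H2A feature at 2.04. Extracellular matrix had -0.01 (adjusted p = 0.742), with a collagen alpha feature at -2.58 and a fibronectin type 3 and ankyrin repeat protein, which is no matrix protein, at -1.41.

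Of the remaining cell type markers none passed as a list over all features. Neoblast and proliferation markers, for the planarian stem cells, had a median of -0.16 (adjusted p = 0.275), with a vasa-like feature at -0.01, and CyclinA-like passed when adjusted over the list alone. Intestinal markers had -0.10 (adjusted p = 0.778), with a trypsin-like protease at -1.52, and ferritin passed when adjusted over the list alone. Eye markers had 0.30 (adjusted p = 0.389), with an orphan rhodopsin-like receptor at 0.84 and beta arrestin 1, which is not specific to eyes, at 5.96. Protonephridial markers had 0.49 (adjusted p = 0.426), with cubilin passing both over all features and when adjusted over the list alone. That list passed as higher with voom (adjusted p = 0.0369, and 0.0231 on the deposited scale; adjusted p = 0.506 and 0.574 with an estimated correlation) and not with at least 100 fragments (0.123), where aquaporin was higher and Slc22a-6 lower when adjusted over the 7 features of the list alone (both 0.0245) but not over all 7982 (0.128 and 0.129). Mucin and secretory markers had -0.10 (adjusted p = 0.911), with a tetraspanin at 6.57 and a mucin-like protein at -0.81. Cubilin was the only list member that passed over all features, and the tested lists for which no such member is given had none past the threshold when adjusted over the list alone in the fit over all features. Median, mean and test differed in sign for innexins, homeobox genes, extracellular matrix, ribosomal proteins, oxidative phosphorylation, innate immunity, protonephridial and mucin markers.

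A count without a test gave 1976 features (12.6%) at least 2-fold apart in the same direction in both numbered pairs, 1007 higher and 969 lower, and 1920 in the crossed pairs. As many as 3706 features differed 2-fold between the control libraries alone and 4561 between the BaCl2 libraries alone. A total of 1031 differed in the same direction between replicates 1 and 2 of both groups. Among features with at least 100 fragments 445 were 2-fold apart in the numbered pairs (141 higher and 304 lower), 114 higher and 285 lower in the crossed pairs, and 57 between the replicates of both groups.

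The authors' deposited comparison, pooled over replicates, had 543 features with a q-value under 0.05. Of these 109 were higher and 205 lower, and 229 had a blank BaCl2 value, 119 of them with the BaCl2 libraries at 0 and 110 with the control libraries at 0. Tubulins made up 9 of the lower and 2 of the higher features. The limma fit over all features shared 18 of the 543, the fit with at least 100 fragments 57 and voom 115. The blank features had a median of 16 fragments.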

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

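The alternatives on fragment or length minimums, voom and those of the fit with at least 100 fragments were chosen after seeing the data. The 20 features called over all features became 0 with a pseudocount of 5 (1876 at unadjusted p under 0.05), 0 with a replicate block (1575) and 0 without any 1 of the 4 libraries (1048 to 2407). Whether equal replicate numbers mark a shared day or culture is not known. The deviations of same-number libraries correlated across features at 0.0244, and at 0.145 with at least 100 fragments, so a shared batch is not excluded. Fewer, deeper features gave 36 calls at 200 nt or more, 87 at 400 nt or more, 51 with at least 40 fragments and 113 with at least 100, and voom gave 144, of which 4 were among the 20, or 211 with the libraries scaled as deposited. The 113 (16 higher and 97 lower) became 948 with the replicate block (404 and 544), 45 with median-ratio rescaling, 53 and 177 with pseudocounts 0.1 and 5, and 225 to 957 with each library left out. The count of 2-fold features (1976) was 1229 with a pseudocount of 5 and 445 with at least 100 fragments, and the deposited comparison (543) had 215 features at a q-value under 0.01 and 318 with at least 100 fragments. The 7 lists called became 4 at a mean of at least 5 FPKM, 4 with at least 100 fragments (tubulins, cilia, muscle and, not among the 7, calcium sensing), 11 with voom (the 7, calcium sensing, ribosomal proteins, oxidative phosphorylation and protonephridial markers), 0 with an estimated correlation, and 4 to 6 with each library left out. The 7 lists kept their direction in each setting in which they were tested, and potassium and voltage-gated channels had too few features with at least 100 fragments. With a pseudocount of 0.1, median-ratio rescaling, the block and each library left out, 0 of 168 values were reversed for the 24 features named by the first rule and 0 of 140 for the 20 of the second. Each of these features differed in the same direction in all 4 library pairs, so a reversal could hardly occur. Adjusted over all features, SPSB missed the threshold with the replicate block (adjusted p = 0.277) and with each library left out (0.183 to 0.283), though its fall stayed at 499- to 508-fold there against 504-fold. Rescaling moved the median log2 fold of all features from -0.057 to 0.027, and of those with at least 100 fragments from -0.15 to -0.059, and voom on library totals moved folds up by a median of 0.20. The causes were not tested, apart from the smaller number of features tested. Depth limits the short features: a single fragment at 100 nt stood for 22.3 FPKM in the shallowest library, and a 4-fold change was called in 2% to 6% of simulated features over all features against 96% to 100% with at least 100 fragments.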

Other observations

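The tests of gene ontology terms, of counting noise and scaling for the tubulins, and of reads moved to another ferritin feature were chosen after the results were seen. The deposited gene ontology terms described further groups among the features with at least 100 fragments, where 15 of 135 terms passed camera with the preset correlation, 4 higher and 11 lower (limma). Features with the term proteinaceous extracellular matrix were higher, with 13 of 16 above 0 and a median log2 fold of 0.70 (adjusted p = 0.00115), as were structural constituents of the matrix (0.75, 10 of 12 above 0, adjusted p = 0.00493), cell adhesion (0.45, 11 of 13 above 0, adjusted p = 0.00614) and calcium ion binding (0.04, 51 of 98 above 0, adjusted p = 0.0246). The extracellular matrix list matched by names did not share this, with a median of -0.01, 4 of 9 above 0 and adjusted p = 0.667 among the same features. DNA repair was lower, with 2 of 22 features above 0 and a median of -0.69 (adjusted p = 0.00356). DNA replication (-0.63, 1 of 17 above 0, adjusted p = 0.00951) and the nucleolus, where ribosomes are assembled (-0.58, 2 of 17 above 0, adjusted p = 0.00447), were lower too. With an estimated correlation, which leaves camera only the 2 residual degrees of freedom, 0 of the 135 terms passed (adjusted p = 0.986). All of these terms were noticed and tested on the same libraries.

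The tubulin list was lower in camera with the preset correlation (adjusted p = 0.600 with an estimated one), 16 of its 39 features with at least 100 fragments fell and 23 did not pass. Counting noise and scaling are argued against as the whole cause, since the median log2 fold was -2.29 in the 39 tubulins with at least 100 fragments and -2.05 after median-ratio rescaling. Reads that moved between tubulin copies stay open: 2 tubulin alpha features that passed as higher with voom had 134 and 151 CPM in control and 379 and 501 CPM in BaCl2 heads, the BaCl2 to control ratio of all tubulin fragments was 0.79 to 1.11 over the library pairs (mean ratio 0.946), and the 624 CPM lost by the 39 of all 55 features with a log2 fold under -1 were less than the range of 2255 CPM between the BaCl2 libraries. The 16 that fell had a mean of 470 CPM in control and 54.6 CPM in BaCl2 heads. Fewer ciliated cells may play a part, with 4 intraflagellar transport features at a median of -0.53 (-0.86 to -0.45), which lies between the bounds set for and against it. Voom on library totals gave these 4 log2 folds from -0.81 to -0.21, and TCONS_00009545 and TCONS_00009544 among them share 1 name. The gene ontology term dynein complex had a median of -0.21 (12 of 31 above 0) and microtubule-based movement -0.46 (5 of 30). Neither passed camera with the preset correlation (adjusted p = 0.909 and 0.0886). Less male germline may play a part too, with 10 features at a median of -0.80 (-2.05 to -0.04, none above 0). Of these 9 were named for sperm, testis or meiosis, among them spermatogenesis-associated protein 17 at -0.83, and 1 was a rhophilin associated tail protein. Sperm flagellar protein 1 and sperm associated antigen 1 also match the cilia and epidermal list, so this median cannot tell male germline from ciliated cells. Nothing in the labels gives the worms' sexual state.

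The neuronal, potassium and voltage-gated channel lists were higher in camera with the preset correlation and the calcium-sensing list was not (adjusted p = 0.128). With an estimated correlation each of the 4 had adjusted p = 0.600, and with at least 100 fragments the neuronal list did not pass (adjusted p = 0.0977). Counting noise in features with few fragments is argued against as the whole cause. The 34 features of these lists with at least 100 fragments had a median of 0.44, with 25 above 0. Length is argued against as well, since 10000 random sets matched on length and fragments had a median of -0.12 (highest 2.5% from 0.11). The median of the lists lay at percentile 100 of these sets. The lists were grouped for being higher in these same libraries, so neither that percentile nor the median of 0.44 is a test of their rise. The calcium-sensing list passed camera (preset correlation) among the features with at least 100 fragments (adjusted p = 0.0453) and not over all features. A larger share of nervous tissue may contribute but stays open, with 72.2% of the 18 neuronal markers above 0, between the bounds set for and against it. A changed share of nervous tissue cannot be told apart from changed expression within cells, because each library was made from whole heads.

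The ferritin and SPSB features were nearly absent from both BaCl2 libraries. Reads moved to another ferritin feature are argued against, since what the other 4 ferritin features gained in CPM was 4.15% to 5.39% of what was lost (617 and 588 CPM in control, 702 and 703 CPM in BaCl2 heads), and on the deposited scale they did not gain in both libraries (304 and 260 against 251 and 310 FPKM). A sequence variant or gene copy replaced by another, as between stocks of worms, may account for such all-or-none features and stays open. All 5 ferritin features together fell at least 3.77-fold over the 4 library pairs, which lies between the bounds set, and the fall of SPSB fragments by at least 383-fold says nothing here, since only 1 feature has that name. The feature sequences, which would tell, were not part of the values used here, and neither the stocks nor feeding over the 35 days were tested.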
